A study of Drosophila melanogaster with 5 samples.

How the data were processed

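The data were 5 single-cell RNA-seq libraries from adult Drosophila ovaries, made with 10x Genomics kits. Per the labels' protocols, the flies were w; His2AV:GFP/+ females aged 2 to 3 days, kept at 25 °C and given yeast for 24 to 48 hours, and each library came from the anterior parts of 30 to 40 pairs of ovaries. Protocol A (n = 2 libraries, made on separate days) used 15 minutes of collagenase and trypsin, a strainer of about 40 µm, flow sorting and the v2 kit. Protocol B (n = 3 libraries, made in parallel on 1 day) used 30 minutes of collagenase and elastase, filters of 70 and 30 µm, no sort and the v3 kit. Protocol, kit, sort, enzyme, filter and day therefore changed together, and no comparison between the protocols separates them. The library is the replicate throughout.

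The deposited matrices hold raw UMI counts per gene and barcode, for the same 17433 genes in all 5 libraries. Per the submitters' processing notes, they were made with bcl2fastq and Cell Ranger on the build dm6, and Seurat was used afterwards. Per the file headers, the protocol B matrices came from software version 3.0.0, and the protocol A matrices state no version. No source states how barcodes were called. The lowest total per barcode was 6299 and 12332 UMIs in protocol A replicates 1 and 2, and 500 in each protocol B library.

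The libraries held 1955 and 1052 barcodes (protocol A) and 12832, 13379 and 13811 barcodes (protocol B), with 39315700, 47507457, 145608845, 148268768 and 143784372 UMIs. Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept. The mitochondrial limit removed 4 and 0 barcodes of protocol A (0.205% and 0%) and 3318, 3091 and 2487 of protocol B (25.9%, 23.1% and 18.0%). Doublets were scored per library with Scrublet in scanpy 1.11.5. The automatic threshold marked under 0.5% of each library, so the barcodes with the highest scores were removed at an expected rate of 0.8% per 1000 barcodes: 30, 9, 695, 822 and 992. This left 1921, 1043, 8625, 9316 and 10142 cells, 31047 in all, with median UMI counts of 15998, 37746, 11949, 10968 and 9761 and median gene counts of 2647, 3779, 2264, 2162 and 2055. Across all cells, the protocol B libraries differed from each other by 4.84 to 6.58 times the counting variance, the 2 protocol A libraries by 85.6 times, and libraries of different protocols by 511 to 753 times. Each fit between the protocols used 1 dispersion (spread between libraries) per gene for both groups. Their SEs and p-values thus measure spread between days only through the 2 protocol A libraries.

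To keep clustering and testing apart, a seeded random draw opened 8429 genes to clustering, with the cell class markers always open and the members of the tested gene lists always closed. The other 9004 genes were kept out of clustering, and comparisons between clusters or classes tested only those. Counts were scaled to the same total per cell and log transformed, the 1500 most variable open genes and the markers were scaled per gene within each library, clipped at 10, and reduced to 30 principal components. A graph of 20 nearest neighbours was cut with the Leiden method (leidenalg 0.10.2, igraph 0.11.9, resolution 1, seed 1) into 20 clusters. Cluster numbers are names only.

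Clusters were named from marker lists for 14 cell classes that were written before any count was read. A name needed at least 3 detected markers (10 CPM or more), at least 2 of them raised 2-fold or more over all other cells, the largest share of raised markers of any class, and the most markers of any class among the 10 genes with the highest fold, at least 1 unless all markers of the class were raised. A cluster with a median UMI count under 1/3 of its own libraries' median kept a name only with over 50% of the markers raised and 1 among those 10 genes. The thresholds of this rule were set after the clusters were seen. Clusters without a name entered no comparison of named classes.

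Counts were summed per library and class, or cluster, where it held at least 20 cells in that library. Sums were compared with quasi-likelihood fits in edgeR 4.0.16 (R 4.3.3), with TMM factors, the default low-count filter and, between classes, the library as a block. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The SE of a log2 fold change was its size divided by the square root of F, and ± after a log2 fold change is this SE. CPM use all UMIs of a sum as the total and are given as mean ± SD over libraries, so a ratio of CPM differs from the TMM-scaled fold. Between classes only protocol A replicate 1 and the 3 protocol B libraries had both sides of comparisons with early follicle-like cells. Of 12 comparisons 7 were planned before any count was read and 5 were added after the clusters were seen, each because a planned one lacked cells or because the germline split into several clusters.

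Lists of genes (26, written before the comparisons were run) were tested with camera in limma 3.58.1 where at least 5 members were tested, with a preset correlation of 0.01 between genes, and adjusted over the lists of a comparison. Each list result is followed by its adjusted p with the correlation estimated from the data. No list in any comparison was past 0.05 with the estimated correlation. Rises and falls within a list count genes past the threshold over all tested genes, and "adjusted over the list alone" gives the counts when only its members are adjusted.

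Genes were named by a fixed rule: the 8 largest log2 fold changes each way among genes past the threshold, with the same direction in every library (between protocols, no overlap of log CPM), at least 20 CPM on the higher side and a symbol other than a CG or CR number or a name for an antisense, small or ribosomal RNA, plus the 3 members with the smallest p of each list past its test. The text describes the genes of these sets with the clearest known roles. With 0 counts on 1 side a fold is given as a lower bound at a floor of 3 counts, and with 1 to 3 counts as a ratio with an exact 95% counting interval. Reads of near-identical copies (RpS14a and RpS14b, Prx2540-1 and Prx2540-2) and of overlapping genes may be assigned to either. Positions are from the BDGP6.54 annotation. Some genes or loci may have been withheld from these files.

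The fits were tested on simulated data made from these sums, with known changes put into 200 genes, as many up as down. Genes varied independently, and the real comparisons called more genes than were changed here. The rates below therefore hold for this setting and do not give the share of false calls in the real comparisons. Planned comparisons recovered 82.8% to 99.0% of 4-fold and 42.3% to 98.0% of 2-fold changes, and 2.70% to 7.04% of the genes called were false. Protocol B against A within escort-like cells was the weakest (42.3% of 2-fold changes), and the share of false calls was above 5% for germline-like (7.04%), vitellogenic follicle-like (6.67%) and polar-like (6.12%) against early follicle-like cells.

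Alternatives were DESeq2 1.42.0, RLE factors, library size alone, no low-count filter, no library block, leaving out each library in turn, at least 1000 UMIs, at least 50 cells per sum, doublets kept, resolution 2, low-UMI clusters left out, and protocol A cells matched to the protocol B clusters by correlation. The last 2 and library size alone were added after the data were seen. Planned comparisons of muscle-like cells, of stalk-like cells at resolution 1, of terminal filament/cap-like with escort-like cells at 20 cells and of the protocols within early follicle-like cells were not run, because too few libraries held such cells. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.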

Results

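Of the 20 clusters, 10 were named: 4 as germline-like, 2 as early follicle-like, and 1 each as vitellogenic follicle-like, escort-like, terminal filament/cap-like and polar-like. Germline-like cells were cluster 4 (739 cells, led by blanks, cona, RpS10a, Ant2 and bam) and cluster 13 (540 cells, led by c(3)G, Rbp9 and ovo). The other 2 were cluster 11 (988 cells, led by bru1, ZnT35C, wisp, pgc and osk) and cluster 17 (1588 cells, led by dhd, Jabba, osk and exu, with a median of 1493 UMIs). Clusters 5 and 10 (5002 and 3714 cells) were early follicle-like, cluster 6 (1629 cells) vitellogenic follicle-like, cluster 8 (1022 cells) escort-like, cluster 12 (215 cells) polar-like and cluster 9 (51 cells) terminal filament/cap-like. The other 10 clusters stayed unnamed, among them cluster 18, with 658 of its 659 cells from protocol A replicate 2. Clusters 0, 2 and 14 carried some early follicle cell markers but did not meet the naming rule, clusters 2 and 14 with 1 raised marker each and cluster 0 with 3 of 5 raised, a smaller share than for the stalk (3 of 3). They held 3.08%, 1.98% and 0.963% of protocol A cells and 2.59%, 5.20% and 9.08% of protocol B cells.

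Germline-like cells were compared with early follicle-like cells, the somatic epithelium of the egg chamber (n = 4 libraries each; 3554 and 8710 cells). The gap junction gene zpg, whose product couples germ cells to the soma, was higher by a log2 fold change of 7.25 ± 0.20 (272 ± 64.8 against 1.42 ± 1.10 CPM; adjusted p = 3.5e-07). The synaptonemal complex gene c(3)G rose by 5.30 ± 0.08 (299.9 ± 48.1 against 4.87 ± 0.364 CPM; adjusted p = 1e-07). The gene rhi, whose product marks the source loci of germline piRNAs, rose by 6.76 ± 0.12 (59.9 ± 4.77 against 0.396 ± 0.143 CPM). In the other direction the laminin gene LanA, a building block of the basement membrane that follicle cells lay down, fell by 5.89 ± 0.08 on the log2 scale (9.02 ± 1.15 against 350.4 ± 84.9 CPM). All had the same direction in 4 of 4 libraries.

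Of 4254 tested genes, 3358 were past the threshold, 1706 higher and 1652 lower. Scaled by library size alone the split was 2845 higher and 802 lower, because the median gene then moved up by 0.59. The direction of log2 fold changes of the size of that shift thus depends on the scaling. The larger ones below kept their direction but moved by a like amount. Prosalpha3, COX7C and Hsc70-3 were then at -0.68, -0.77 and -0.51. High genes included SK (7.40 ± 0.17) and SLO2 (7.27 ± 0.16), which encode potassium channels, and Jabba (7.32 ± 0.12), which holds histones on lipid droplets. They also included plu (7.28 ± 0.21), a regulator of embryonic S phase, and the linker histone gene BigH1 (7.11 ± 0.22). Genes of mRNA localisation and of poly(A) control were raised as well: swa (7.05 ± 0.12), exu (6.43 ± 0.12) and the poly(A) polymerase gene wisp (6.52 ± 0.15). With rhi rose its partner del (6.16 ± 0.15) and the piRNA amplification gene qin (6.77 ± 0.14), and with c(3)G rose cona (5.58 ± 0.12) and mtrm (5.19 ± 0.08). The germline paralogs RpS10a (6.22 ± 0.12) and RpS19b (4.22 ± 0.15) and the cytochrome gene Cyt-c1L (4.95 ± 0.14) stood out from their families, which fell.

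Of the lower genes named here, the lowest were nord (-7.19 ± 0.21), stl (-6.83 ± 0.13), Cyp6d2 (-6.80 ± 0.13), bdl (-6.72 ± 0.16) and the ecdysone synthesis gene phm (-6.38 ± 0.18). Basement membrane genes were far lower in the germline, with Col4a1 at -5.74 ± 0.09 and the collagen hydroxylase gene PH4alphaEFB at -5.02 ± 0.06, along with dally (-6.26 ± 0.10), which encodes a surface proteoglycan. So were the transcription factor genes h (-6.22 ± 0.11), peb (-4.23 ± 0.12) and br (-4.12 ± 0.09), and, of Notch signalling, fng (-3.67 ± 0.12) and N itself (-2.40 ± 0.07; 183 ± 11.8 against 636 ± 58.4 CPM). Smaller falls were found in Prosalpha3 (-1.28 ± 0.05), COX7C (-1.37 ± 0.04) and Hsc70-3 (-1.10 ± 0.05).

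Among gene lists, 18 of 20 tested meiosis genes rose and 2 fell (adjusted p = 4.61e-06, and adjusted p = 0.458 with an estimated correlation). Of 31 piRNA pathway genes 19 rose and 6 fell (adjusted p = 0.0138, and adjusted p = 0.458 with an estimated correlation). Of 23 oocyte mRNA localisation genes 15 rose and 5 fell (adjusted p = 0.0167, and adjusted p = 0.626 with an estimated correlation). No basement membrane gene rose and 16 of 19 fell (adjusted p = 4.61e-06, and adjusted p = 0.451 with an estimated correlation). Notch signalling (17 genes, 3 up, 13 down, adjusted p = 0.00493) and ecdysone signalling (24 genes, 5 up, 16 down, adjusted p = 0.0119) were lower too (adjusted p = 0.292 for both with an estimated correlation). Ribosomal proteins fell in 82 of 86 genes and rose in 4 (adjusted p = 1.59e-12, and adjusted p = 0.531 with an estimated correlation). Oxidative phosphorylation genes fell in 66 of 70 and rose in 4 (adjusted p = 3.34e-13, and adjusted p = 0.267 with an estimated correlation). The proteasome (34 genes, 2 up, 32 down, adjusted p = 2.67e-07) and heat shock genes (18 genes, 1 up, 14 down, adjusted p = 0.00423) followed (adjusted p = 0.292 for both with an estimated correlation). Mitochondrially encoded transcripts were lower in 15 of 16 genes and higher in 1 (adjusted p = 0.000339, and adjusted p = 0.485 with an estimated correlation, and 0.0859 without the library block). With library size alone, the median fold change of these families kept its sign but shrank, from -0.70 to -0.10 for ribosomal proteins and from -0.89 to -0.30 for oxidative phosphorylation. The counts were the same adjusted over the list alone. The other 14 of 25 lists were not past the threshold.

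**Figure D1:**
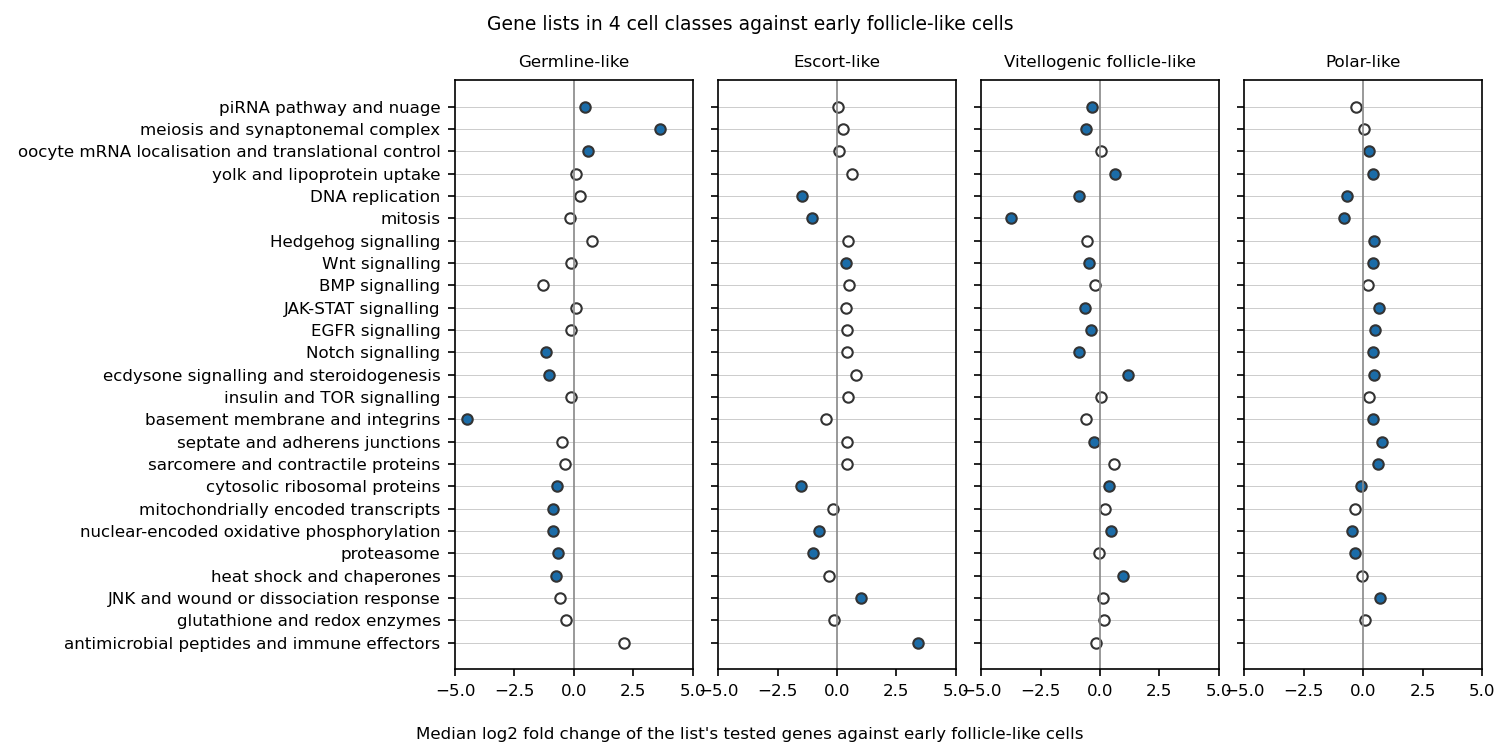
Median log2 fold change of the tested genes of each list (horizontal axis), in 4 panels for germline-like, escort-like, vitellogenic follicle-like and polar-like cells, each against early follicle-like cells. Filled points are lists with an adjusted p under 0.05 at the preset correlation, open points the others; meiosis genes lie at 3.62 in the germline panel and mitosis genes at -3.75 in the vitellogenic panel.

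Escort-like cells, the somatic cells that enwrap young germline cysts in the germarium, were set against the same early follicle-like cells (n = 4 libraries; 1002 and 8710 cells). Vago, whose product is secreted in antiviral defence, rose by a log2 fold change of 9.61 ± 0.17 (381 ± 94.2 against 0.33 ± 0.186 CPM; adjusted p = 9.9e-10). The peroxidase gene Irc, which acts in gut immunity, rose by 9.62 ± 0.15 (136 ± 38.3 against 0.0971 ± 0.0114 CPM; adjusted p = 6.9e-10). The ligand gene Wnt2 was higher by 5.64 ± 0.10 (186 ± 46.9 against 2.39 ± 0.321 CPM). Among lower genes was again nord (-5.48 ± 0.19; adjusted p = 3.3e-08). Each direction held in 4 of 4 libraries.

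Of 3811 tested genes, 2774 were past the threshold, 1345 higher and 1429 lower. With library size alone the split was 2257 higher and 750 lower, with a median shift of 0.60, and without the low-count filter the median shifted by -0.13. High genes also included Syn (8.59 ± 0.27), bin (8.44 ± 0.51), Slc45-1 (8.68 ± 0.17), rdo (8.27 ± 0.45) and yellow-d (8.26 ± 0.27). Hf was found with 247 counts against 3 (1439-fold, counting interval 487 to 7026). The peptidoglycan sensor gene PGRP-SA (7.99 ± 0.24), the immune regulator gene pirk (7.16 ± 0.31) and the NF-kappaB gene dl (4.20 ± 0.18) rose together, as did the Wnt pathway genes fz3 (6.79 ± 0.21) and wls (3.06 ± 0.08). Stress response genes were raised: Gadd45 (3.34 ± 0.08), kay (2.36 ± 0.08) and Xrp1 (2.09 ± 0.08; 806 ± 178 against 123 ± 8.16 CPM). Lower genes included the ecdysone synthesis genes phm (-4.61 ± 0.27) and sro (-4.39 ± 0.20), the transcription factor gene klu (-4.17 ± 0.22), the filamin-like gene jbug (-3.99 ± 0.16), Cyp6d2 (-4.93 ± 0.25) and Mipp1 (-4.62 ± 0.17). With doublets kept these 6 genes and nord were lower by less, between -2.29 (sro) and -3.14 (nord). Genes of cell division and growth were lower by less: Mcm7 (-1.99 ± 0.13), fzy (-1.88 ± 0.12), Mcm6 (-1.68 ± 0.10), aurB (-1.51 ± 0.09), RpL11 (-2.03 ± 0.07), RpS16 (-1.61 ± 0.06) and Cyt-c-p (-2.19 ± 0.10). With library size alone Mcm6, aurB and RpS16 were at -1.08, -0.91 and -1.01.

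All 24 DNA replication genes fell (adjusted p = 0.000253, and adjusted p = 0.454 with an estimated correlation), as did 27 of 32 mitosis genes with none rising (adjusted p = 0.00047, and adjusted p = 0.434 with an estimated correlation). Ribosomal proteins fell in 82 of 85 genes and rose in 3 (adjusted p = 2.68e-42, and adjusted p = 0.434 with an estimated correlation). Oxidative phosphorylation genes fell in 65 of 67 with 0 rising (adjusted p = 4.41e-10, and adjusted p = 0.215 with an estimated correlation). The proteasome fell in 31 of 32 with 0 rising (adjusted p = 1.83e-08, and adjusted p = 0.434 with an estimated correlation). Under library size alone the ribosomal median went from -1.51 to -0.91, the oxidative phosphorylation median from -0.75 to -0.15 and the proteasome median from -1.02 to -0.42. Wnt signalling was higher, with 12 of 19 genes up and 0 down (adjusted p = 0.000591, and adjusted p = 0.329 with an estimated correlation). So were the JNK and dissociation response (18 genes, 13 up, 2 down, adjusted p = 0.00332) and immune effectors (6 of 6 up; adjusted p = 0.00047), both at adjusted p = 0.434 with an estimated correlation. Escort-like cells also had fewer UMIs (median 4533 against 11036 and 11389 in clusters 5 and 10) and more mitochondrial UMIs (7.48% against 4.50% and 4.54%), so these lists do not separate cell class from RNA quality. Adjusted over the list alone, all counts were the same. The other 17 of 25 lists were not past the threshold, among them ecdysone signalling (23 genes, 15 up, 6 down, adjusted p = 0.385).

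Terminal filament/cap-like cells, the somatic niche of the germline stem cells, had too few cells for the planned minimum, and the comparison with escort-like cells was run after seeing this, at a minimum of 8 cells (n = 4 libraries; 50 and 1002 cells). The ligand gene dpp, the niche signal that keeps germline stem cells, held 52 counts against 2 (660-fold, counting interval 174 to 5591), and wg held 20 against 0 (at least 169-fold). The allatostatin C receptor gene AstC-R2 had 34 counts against 0 (at least 288-fold) and the cuticle protein gene Cpr78E 16 against 0 (at least 135-fold). Among genes with counts on both sides, the transglutaminase gene Tg rose by a log2 fold change of 7.53 ± 0.59, Mipp1 by 7.38 ± 0.33, dpr8 by 6.98 ± 0.64 and Kul by 5.19 ± 0.80. The BMP antagonist gene sog (4.26 ± 0.31) and the BMP co-receptor gene dally (1.34 ± 0.30) were also higher, with CAP (4.50 ± 0.38), LanB2 (2.77 ± 0.29), vkg (1.86 ± 0.26), Msp300 (2.39 ± 0.26), cora (1.75 ± 0.25) and Hsp68 (2.28 ± 0.25). Timp (-3.10 ± 0.33), vari (-2.24 ± 0.33), stg (-1.94 ± 0.31) and ATPsynbeta (-1.12 ± 0.27) were lower, and wun2 held 2 counts against 2237 (44.1-fold, counting interval 12.2 to 364). The smallest sum held 46287 UMIs. Of 3070 tested genes, 468 were past the threshold, 234 each way. With DESeq2 196 were higher and 117 lower, and with library size alone 267 and 190, at a median shift of 0.10. Without the low-count filter the median shifted by -0.15.

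Basement membrane genes were higher there (18 tested, 8 up, 3 down, and 9 and 3 adjusted over the list alone, adjusted p = 0.0031, and 0.513 with an estimated correlation). So were sarcomere genes (12 tested, 6 up, 0 down, and 6 and 1 adjusted over the list alone, adjusted p = 0.000649, and 0.513 with an estimated correlation). BMP signalling was higher too (15 tested, 5 up, 1 down, the same adjusted over the list alone, adjusted p = 0.0276, and 0.59 with an estimated correlation). Mitosis genes were lower (26 tested, 0 up, 6 down, and 0 and 10 adjusted over the list alone, adjusted p = 0.00223, and 0.616 with an estimated correlation). So were oxidative phosphorylation genes (64 tested, 0 up, 15 down, and 0 and 19 adjusted over the list alone, adjusted p = 2.31e-05, and 0.613 with an estimated correlation). Ribosomal proteins were lower too (84 tested, 0 up, 3 down, and 0 and 0 adjusted over the list alone, adjusted p = 3.83e-09, and 0.734 with an estimated correlation). Heat shock genes (17 tested, 4 up, 0 down, adjusted p = 0.0276, and 0.513 with an estimated correlation) were lost without protocol A replicate 1 (adjusted p = 0.0948). Septate and adherens junctions (26 tested, 6 up, 3 down, adjusted p = 0.0388, and 0.613 with an estimated correlation) were lost without protocol B replicate 2 (adjusted p = 0.155). Both had the same counts adjusted over the list alone. Terminal filament/cap-like cluster 9 had a median of 1954 UMIs and 9.53% mitochondrial UMIs against 4533 and 7.48% in escort-like cluster 8, so these lists do not separate cell class from RNA quality. Cluster 9 also had 4 of 5 muscle-like and 3 of 5 oviduct-like markers raised. The rises of sarcomere genes, Msp300 and CAP are therefore not separated from RNA of other cell types. The other 16 of 24 lists were not past the threshold.

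Vitellogenic follicle-like cells, the follicle epithelium of later egg chambers, were compared with early follicle-like cells (n = 4 libraries; 1624 and 8710 cells). The fatty acid elongase gene bond rose by a log2 fold change of 8.86 ± 0.08 (194 ± 8.46 against 0.539 ± 0.061 CPM; adjusted p = 4.2e-10). The genes spo and sad, which encode enzymes of ecdysone synthesis, rose by 8.24 ± 0.11 (134 ± 46.9 against 0.613 ± 0.0772 CPM) and 6.97 ± 0.12. The anaphase activator gene fzy fell by 4.77 ± 0.08 on the log2 scale (2.35 ± 0.876 against 73.4 ± 7.43 CPM), and the Notch target gene E(spl)m7-HLH by 5.83 ± 0.09 (2.06 ± 0.924 against 147 ± 67.8 CPM). All had the same direction in 4 of 4 libraries. The class markers that gave these cells their name, yolk protein and vitelline membrane genes, made up 5.07 ± 1.65% of their UMIs, and so bear on every CPM of the class.

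Of 3883 tested genes, 2950 were past the threshold, 1478 higher and 1472 lower. With library size alone the split was 833 higher and 2294 lower, at a median shift of -0.34. Other high genes were slbo (6.95 ± 0.25), the transcription factor gene of border cell migration, nemy (6.34 ± 0.11) and wdp (5.92 ± 0.11). They were followed by the glutathione transferase gene GstO3 (5.75 ± 0.15), GlcAT-P (5.74 ± 0.13) and ImpL2 (5.34 ± 0.16), whose product binds insulin-like peptides. The lipoprotein receptor gene LpR1 (2.69 ± 0.17) and the lipid droplet gene Lsd-2 (2.02 ± 0.08) rose, and so did Hsp68 (2.00 ± 0.11) and DnaJ-1 (1.75 ± 0.04). Lower genes were bdl (-6.92 ± 0.14), Spn42Dd (-6.45 ± 0.13), Cyp6d2 (-6.14 ± 0.11), Cks30A (-5.80 ± 0.09), mei-38 (-5.69 ± 0.20), the securin gene pim (-5.41 ± 0.15) and Ugt58Fa (-5.18 ± 0.08). Incenp (-4.14 ± 0.06) and ncd (-3.91 ± 0.07) followed, with RPA2 (-1.77 ± 0.04) and geminin (-1.65 ± 0.05) of DNA replication. N fell by 1.93 ± 0.06 and E(spl)m3-HLH by 2.80 ± 0.05. The somatic piRNA genes armi (-3.48 ± 0.05), piwi (-2.89 ± 0.06) and zuc (-2.29 ± 0.08), the Wnt receptor gene fz2 (-3.40 ± 0.09), spi (-2.67 ± 0.06), apt (-2.56 ± 0.08), ed (-2.36 ± 0.07) and Socs36E (-2.33 ± 0.05) were lower as well.

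All 32 mitosis genes fell (adjusted p = 1.95e-10, and adjusted p = 0.422 with an estimated correlation), and 21 of 24 DNA replication genes fell and 1 rose (adjusted p = 2.51e-05, and adjusted p = 0.381 with an estimated correlation). Notch signalling fell in 13 of 17 genes and rose in 2 (adjusted p = 0.00451, and adjusted p = 0.412 with an estimated correlation). Ribosomal proteins rose in 82 of 85 genes and fell in 3 (adjusted p = 1.78e-15) and oxidative phosphorylation rose in 63 of 67 and fell in 2 (adjusted p = 5.15e-14). Heat shock genes rose in 16 of 19 and fell in 1 (adjusted p = 0.000739). These 3 lists were each at adjusted p = 0.381 with an estimated correlation. Their medians went from 0.39 to 0.06, from 0.47 to 0.14 and from 0.97 to 0.63 under library size alone. A further 8 lists passed with adjusted p above 0.02 and lost the call in at least 1 other setting. Those lower were meiosis (14 genes, 0 up, 11 down, adjusted p = 0.0228, 0.412 with an estimated correlation, 0.11 with library size alone) and piRNA (28 genes, 5 up, 19 down, and 6 and 19 adjusted over the list alone, adjusted p = 0.0361, 0.422 with an estimated correlation, 0.0663 without protocol A replicate 1). EGFR signalling was lower (20 genes, 3 up, 11 down, and 2 and 11 adjusted over the list alone, adjusted p = 0.0207, 0.381 with an estimated correlation, 0.13 with doublets kept), with Wnt signalling (19 genes, 3 up, 13 down, adjusted p = 0.0308, 0.422 with an estimated correlation, 0.125 with library size alone). JAK-STAT signalling was lower as well (12 genes, 1 up, 8 down, adjusted p = 0.0422, 0.412 with an estimated correlation, 0.145 with library size alone), and so were septate and adherens junctions (28 genes, 6 up, 15 down, adjusted p = 0.04997, 0.381 with an estimated correlation, 0.494 with doublets kept). Of the 2 higher lists, 1 was ecdysone signalling (26 genes, 16 up, 7 down, adjusted p = 0.0475, 0.422 with an estimated correlation, 0.0508 with RLE factors). The last was yolk and lipoprotein uptake (13 genes, 10 up, 2 down, adjusted p = 0.0475, 0.422 with an estimated correlation, 0.0757 without the library block). The counts of all other lists were the same adjusted over the list alone, and the remaining 11 of 25 lists were not past the threshold.

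Polar-like cells, the signalling cells at the ends of the egg chamber, were compared with early follicle-like cells (n = 4 libraries; 197 and 8710 cells). The potassium channel subunit gene Hk rose by a log2 fold change of 8.64 ± 0.16 (111 ± 25.0 against 0.311 ± 0.254 CPM; adjusted p = 1.3e-14). The gene wb, which encodes a second laminin alpha chain, rose by 5.16 ± 0.08 (381 ± 50.8 against 9.89 ± 0.167 CPM; adjusted p = 1.1e-15). The JAK-STAT receptor gene dome, which receives the ligand that polar cells secrete, was higher by 1.29 ± 0.07 and its feedback inhibitor gene Socs36E by 0.94 ± 0.06. Among the lower genes named, the antioxidant gene Sod3 fell the most, at -1.75 ± 0.09 (82.4 ± 22.1 against 262 ± 13.4 CPM). All had the same direction in 4 of 4 libraries.

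Of 3678 tested genes, 2037 were past the threshold, 1010 higher and 1027 lower (1229 and 796 with library size alone, at a median shift of 0.11). High genes besides Hk were Spn43Aa (8.11 ± 0.22), slbo (7.32 ± 0.39), pgant2 (7.10 ± 0.20), dpn (6.54 ± 0.25) and pigs (5.75 ± 0.32). Then came Mmp2 (5.42 ± 0.36), dl (5.41 ± 0.17) and the actin nucleator gene spir (5.37 ± 0.24). Signalling genes were raised in several pathways, with shf (4.26 ± 0.14), fz (3.72 ± 0.13), E(spl)mgamma-HLH (3.23 ± 0.19), E(spl)m7-HLH (2.81 ± 0.16), fng (1.28 ± 0.09), and Egfr (0.76 ± 0.07). So were Sox14 (2.78 ± 0.09), EcR (0.82 ± 0.08) and CrebA (2.67 ± 0.11). Junction and cytoskeleton genes included Lac (2.35 ± 0.12), cno (1.26 ± 0.07) and sls (1.36 ± 0.15). The falls were smaller: bdl (-1.51 ± 0.15), nord (-1.31 ± 0.10), klu (-1.27 ± 0.11, and -0.78 at resolution 2), CycB (-1.20 ± 0.12) and aurB (-1.13 ± 0.08). The phosphatase gene stg (-1.11 ± 0.07) was lower with Cdk1 (-0.85 ± 0.06), COX5B (-0.71 ± 0.06) and Prosalpha5 (-0.60 ± 0.06).

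Septate and adherens junction genes rose in 21 of 27 and fell in 1 (adjusted p = 1.61e-07, and adjusted p = 0.147 with an estimated correlation). JAK-STAT signalling rose in 7 of 11 genes with 0 falling (adjusted p = 0.000265) and the JNK response in 13 of 19 with 2 falling (adjusted p = 0.00046), both at adjusted p = 0.147 with an estimated correlation. Sarcomere genes rose in 8 of 11 with 0 falling (adjusted p = 0.00316) and ecdysone signalling in 12 of 22 with 3 falling (13 and 3 adjusted over the list alone, adjusted p = 0.00494), each at adjusted p = 0.147 with an estimated correlation. EGFR signalling (20 genes, 10 up, 0 down, adjusted p = 0.00388) and Notch signalling (19 genes, 10 up, 3 down, adjusted p = 0.0191) rose (adjusted p = 0.185 for both with an estimated correlation). Hedgehog signalling rose in 6 of 13 genes with 0 falling (adjusted p = 0.00884, and adjusted p = 0.268 with an estimated correlation). Mitosis genes fell in 26 of 32 (adjusted p = 6.54e-09, and adjusted p = 0.137 with an estimated correlation) and DNA replication genes in 19 of 24 (adjusted p = 1.83e-05, and adjusted p = 0.198 with an estimated correlation), with 0 rising in either. Oxidative phosphorylation fell in 63 of 66 genes and rose in 1 (1 up and 64 down adjusted over the list alone, adjusted p = 6.64e-18, and adjusted p = 0.242 with an estimated correlation). The proteasome fell in 24 of 32 with 0 rising (25 adjusted over the list alone, adjusted p = 4.4e-06, and adjusted p = 0.147 with an estimated correlation). A further 5 lists passed and lost the call in other settings. Those higher were Wnt signalling (17 genes, 9 up, 2 down, adjusted p = 0.0495, 0.268 with an estimated correlation, 0.108 without the library block) and oocyte mRNA localisation (19 genes, 11 up, 3 down, adjusted p = 0.0366, 0.268 with an estimated correlation, 0.0554 without protocol A replicate 1). Yolk and lipoprotein uptake was higher (11 genes, 7 up, 0 down, adjusted p = 0.0366, 0.268 with an estimated correlation, 0.173 without protocol B replicate 3), with the basement membrane (19 genes, 11 up, 5 down, adjusted p = 0.0298, 0.291 with an estimated correlation, 0.06 at resolution 2). Ribosomal proteins were lower (84 genes, 0 up, 15 down, and 0 and 7 adjusted over the list alone, adjusted p = 0.0298, 0.834 with an estimated correlation). The median of the ribosomal proteins changed sign with library size alone, from -0.08 to 0.0073. The counts of the other lists were the same adjusted over the list alone, and 7 of 24 lists were not past the threshold.

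**Figure D2:**
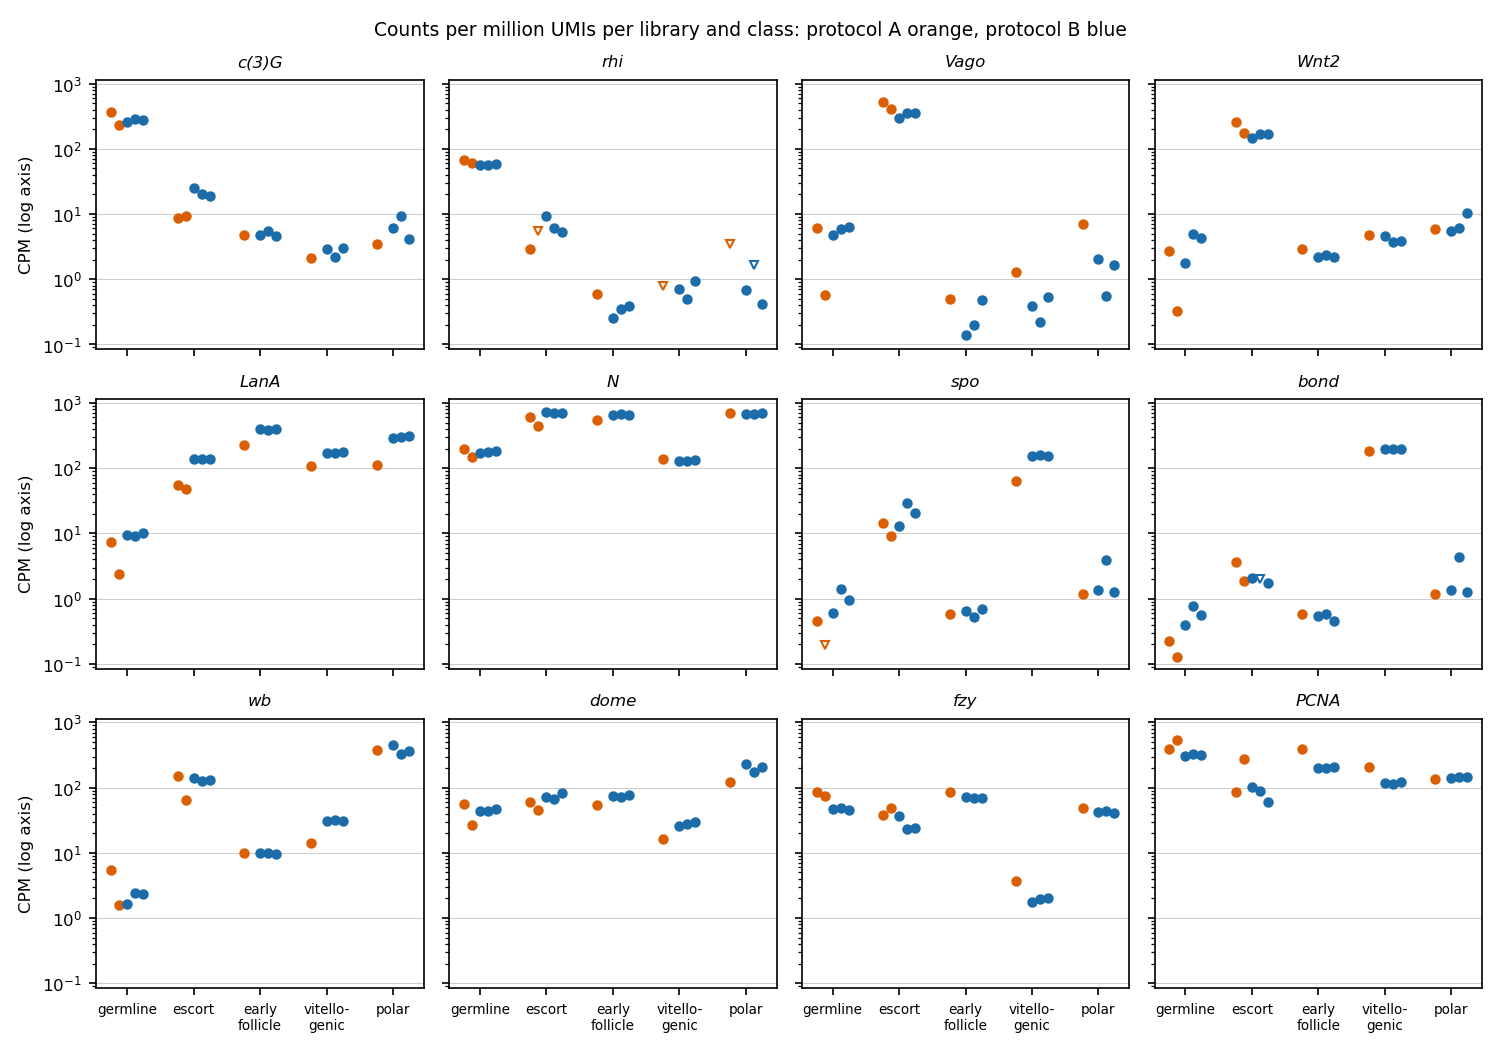
CPM on a log axis of 12 genes in germline-like, escort-like, early follicle-like, vitellogenic follicle-like and polar-like cells, 1 point per library (orange for protocol A, blue for protocol B), with open triangles at the floor of 3 counts for sums with 0 counts. Over the 4 libraries with both classes c(3)G averages 299.9 CPM in germline-like and 4.87 in early follicle-like cells, and libraries with fewer than 20 cells of a class are left out.

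The 2 protocols were compared over all cells first (n = 3 protocol B and 2 protocol A libraries; 28083 and 2964 cells). The snoRNA host transcript Uhg7 (3L, 1666288 to 1667307) was lower in protocol B by 3.74 ± 0.06 on the log2 scale (6.003 ± 0.256 against 81.8 ± 0.615 CPM; adjusted p = 0.00017). The ribosomal protein gene RpL22, on the X chromosome, differed by -3.17 ± 0.13 (179 ± 21.0 against 1643 ± 123 CPM) and the mitochondrial gene mt:ND1, a subunit of complex I, by -2.80 ± 0.12 (87.7 ± 6.96 against 621 ± 69.0 CPM; adjusted p = 0.00069). Higher in protocol B was the vitelline membrane gene Vml, an eggshell gene, at 3.16 ± 0.22 (45.6 ± 3.34 against 5.21 ± 1.42 CPM; adjusted p = 0.0011). For each gene the CPM of the 2 groups of libraries did not overlap. Protocol, kit, sort, filters and day cannot be told apart in any of these values, and the mix of cells differed between libraries.

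Of 9883 tested genes 4239 were past the threshold, 2185 higher and 2054 lower in protocol B (1995 and 2048 with library size alone). Leaving out 1 library gave 7405 genes without protocol A replicate 1, 6706 without replicate 2, and 1940, 1912 and 1880 without the protocol B replicates in turn. With eggshell genes rose psd (1.90 ± 0.51) and ndl (1.89 ± 0.26) and the steroid gene spo (2.16 ± 0.50). Other higher genes were mt:CoII (1.99 ± 0.13), Hsp67Ba (1.86 ± 0.26), e(y)3 (1.78 ± 0.10) and Rab10 (1.67 ± 0.08). LanA (1.03 ± 0.15), LanB2 (1.03 ± 0.12) and Mp (0.93 ± 0.17) of the basement membrane were higher, with Pi3K92E (0.70 ± 0.08), Akt1 (0.69 ± 0.05) and Tsc1 (0.64 ± 0.06) of insulin signalling. Lower were Prx2540-1 (-2.83 ± 0.23), galla-2 (-2.37 ± 0.20), ND-AGGG (-2.23 ± 0.15), RpS14b (-2.21 ± 0.04), RpL5 (-1.79 ± 0.03) and RpL39 (-1.28 ± 0.04). Germline genes were lower as well: cona (-2.24 ± 0.40), Oxp (-2.40 ± 0.41), ord (-1.70 ± 0.28), sunn (-1.61 ± 0.26) and spn-D (-1.04 ± 0.18). Without 1 protocol B replicate in turn, the calls of spo, psd, Mp, spn-D, cona and Oxp were lost at adjusted p between 0.0507 and 0.111, and that of ord without replicates 1 and 3. Without protocol A replicate 1 spo was at 3.25 and psd at 2.99, and without replicate 2 cona was at -1.38 and Oxp at -1.51.

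The insulin and TOR signalling list was higher in protocol B (19 genes, 10 up, 0 down, and 11 and 0 adjusted over the list alone, adjusted p = 0.00217), at adjusted p = 0.938 with an estimated correlation. So was the basement membrane (21 genes, 9 up, 0 down, and 10 and 0 adjusted over the list alone, adjusted p = 0.00781), at adjusted p = 0.938 with an estimated correlation. Ribosomal proteins were split, with 22 of 87 up and 46 down (22 and 47 adjusted over the list alone, adjusted p = 0.00101, and 0.938 with an estimated correlation). Mitosis (32 genes, 5 up, 16 down, and 5 and 19 adjusted over the list alone, adjusted p = 0.0183) and meiosis (20 genes, 0 up, 9 down, the same adjusted over the list alone, adjusted p = 0.012) were lower, both at adjusted p = 0.938 with an estimated correlation. Without protocol A replicate 2, the calls of insulin signalling (adjusted p = 0.338), mitosis (adjusted p = 0.161) and meiosis (adjusted p = 0.319) were lost. The other 21 of 26 lists were not past the threshold.

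Within germline-like cells (n = 3 and 2 libraries; 3350 and 505 cells), the make-up of the class differed between the protocols. Clusters 4, 13, 11 and 17 made up 42.4%, 19.0%, 38.4% and 0.198% of it in protocol A and 15.7%, 13.3%, 23.7% and 47.4% in protocol B. Higher in protocol B were Wnt4 (3.96 ± 0.75; 31.7 ± 11.3 against 3.64 ± 4.69 CPM), ptc (3.96 ± 0.54) and Timp (3.16 ± 0.66), with the steroid response gene Eip93F (4.16 ± 0.62; adjusted p = 0.0012). Wnt4 and ptc are escort cell markers, and Timp was among the leading genes of the escort-like cluster. Escort markers summed to 803 CPM in cluster 4 of protocol B against 164 CPM in protocol A, so these rises are not separated from escort RNA. Uhg7 differed by -4.01 ± 0.09 (5.56 ± 0.489 against 85.8 ± 1.23 CPM; adjusted p = 7.9e-07). The CPM of the 2 groups did not overlap for any of these genes, and the call of Timp was lost with DESeq2 (adjusted p = 0.0664) and with doublets kept (adjusted p = 0.0626). The size of the rises rested on protocol A replicate 2: without it they were 2.20 for Wnt4, 2.51 for ptc, 1.58 for Timp and 2.51 for Eip93F, and without replicate 1 Wnt4 was at 6.49 and Timp at 5.19.

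Of 8272 tested genes 4292 were past the threshold, 2182 higher and 2110 lower (2547 and 1806 with library size alone, at a median shift of 0.07). The Notch response genes E(spl)m2-BFM (2.94 ± 0.28) and E(spl)m3-HLH (2.11 ± 0.38, and 1.19 without protocol A replicate 2) and the chaperone gene stv (2.21 ± 0.34, and 1.40 without protocol A replicate 2) were higher. So were egl (1.05 ± 0.09), sqd (0.92 ± 0.06) and tral (0.84 ± 0.07) of mRNA localisation, and Thor (0.84 ± 0.13), Akt1 (0.63 ± 0.08) and foxo (0.48 ± 0.08) of insulin signalling. The rises of the Notch response genes are likewise not separated from somatic RNA. Lower in protocol B were RpL22 (-3.39 ± 0.11), the ADP/ATP carrier gene Ant2 (-2.75 ± 0.14), mt:ND1 (-2.69 ± 0.17), galla-2 (-2.27 ± 0.21) and blanks (-2.26 ± 0.17). They were joined by nmdyn-D6 (-2.25 ± 0.11), RpS14b (-2.23 ± 0.06) and RpS5a (-2.02 ± 0.05). The meiosis genes cona (-1.59 ± 0.07), hdm (-1.13 ± 0.11) and c(2)M (-0.87 ± 0.12) and the mitosis genes pim (-0.96 ± 0.07), fzy (-0.81 ± 0.08) and aurB (-0.62 ± 0.06) were lower too.

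Oocyte mRNA localisation was higher in protocol B (23 genes, 15 up, 1 down, the same adjusted over the list alone, adjusted p = 0.00766, and 0.736 with an estimated correlation). So was insulin signalling (17 genes, 12 up, 0 down, the same adjusted over the list alone, adjusted p = 0.0122, 0.827 with an estimated correlation, 0.0829 without protocol A replicate 2). Ribosomal proteins were lower (87 genes, 12 up, 51 down, and 14 and 52 adjusted over the list alone, adjusted p = 3.1e-10, and 0.866 with an estimated correlation). Oxidative phosphorylation was also lower (70 genes, 14 up, 30 down, and 15 and 30 adjusted over the list alone, adjusted p = 0.0124, and 0.866 with an estimated correlation). Meiosis (20 genes, 1 up, 10 down, and 1 and 11 adjusted over the list alone, adjusted p = 0.0145, 0.736 with an estimated correlation, 0.0785 with low-UMI clusters left out) was lower. So was mitosis (32 genes, 7 up, 18 down, and 7 and 19 adjusted over the list alone, adjusted p = 0.0393, 0.736 with an estimated correlation, 0.117 without protocol A replicate 2). The other 19 of 25 lists were not past the threshold.

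**Figure D3:**
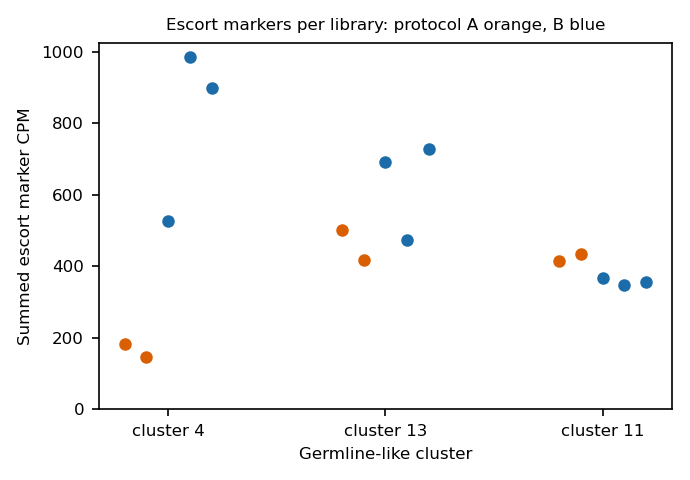
Summed CPM of the escort cell markers (vertical axis) in germline-like clusters 4, 13 and 11, 1 point per library of protocol A and protocol B. In cluster 4 the protocol B libraries averaged 803 CPM (527 to 984) and the protocol A libraries 164 CPM, and in cluster 11 the averages were 357 and 424 CPM.

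Within escort-like cells (n = 3 and 2 libraries; 872 and 150 cells), the collagen IV genes of the basement membrane were higher in protocol B. Col4a1 rose by a log2 fold change of 2.09 ± 0.16 (440 ± 16.5 against 94.5 ± 1.43 CPM; adjusted p = 0.00022). Its partner vkg was higher by 1.72 ± 0.21. The lipocalin gene NLaz rose by 3.10 ± 0.49 (adjusted p = 0.006). Also higher were bru1 of the germline by 2.83 ± 0.52 (94.2 ± 36.8 against 9.60 ± 10.99 CPM), BigH1 by 2.35 ± 0.57 and Vm34Ca of late follicle cells by 2.72 ± 0.64. Uhg7 differed by -4.48 ± 0.35 (adjusted p = 0.00027). The groups did not overlap for these genes. Leaving out a protocol B replicate, the calls were lost for bru1 (adjusted p = 0.0509 without replicate 1), Vm34Ca (0.0994 and 0.104 without replicates 2 and 3), NLaz (0.0513 without replicate 3) and BigH1 (0.122, 0.111 and 0.0692 in turn). That of BigH1 was also lost with doublets kept (0.0750) and at resolution 2 (0.0705). Without protocol A replicate 1 the folds were larger, at 5.45 for bru1 and 6.75 for NLaz. Those of Vm34Ca and BigH1 were too, but replicate 2 had 0 counts of both.

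Of 6592 tested genes 692 were past the threshold, 247 higher and 445 lower (332 and 315 with library size alone, at a median shift of 0.11). Without the low-count filter 1269 genes were past it, and with doublets kept 1064. Leaving out 1 library gave 1578 genes without protocol A replicate 1 (766 higher, 812 lower), 2100 without replicate 2, and 163, 176 and 134 without the protocol B replicates in turn. Higher were also RhoGAP100F (2.54 ± 0.33), RhoGAP1A (2.44 ± 0.38), the netrin gene NetA (2.35 ± 0.30) and the perlecan gene trol (1.66 ± 0.15). Lower in protocol B were RpL22 (-3.70 ± 0.17), Prx2540-1 (-3.55 ± 0.31), mt:ND1 (-3.33 ± 0.25), RpS19a (-2.82 ± 0.21) and the immune protease gene SPE (-2.79 ± 0.37). So were RpS14b (-2.73 ± 0.20), ND-AGGG (-2.56 ± 0.25), RpS5a (-2.22 ± 0.16), ox (-1.37 ± 0.16) and GstE1 (-1.34 ± 0.19). The basement membrane was higher (18 genes, 5 up, 0 down, and 6 and 0 adjusted over the list alone, adjusted p = 4.97e-06, and 0.304 with an estimated correlation). Ribosomal proteins were lower (85 genes, 0 up, 29 down, and 2 and 35 adjusted over the list alone, adjusted p = 2.85e-14, and 0.983 with an estimated correlation), and so was oxidative phosphorylation (66 genes, 0 up, 15 down, and 1 and 20 adjusted over the list alone, adjusted p = 3.06e-06, and 0.983 with an estimated correlation). So were glutathione and redox enzymes (29 genes, 0 up, 11 down, and 0 and 16 adjusted over the list alone, adjusted p = 0.00119, 0.304 with an estimated correlation, 0.0571 without protocol A replicate 1). The other 21 of 25 lists were not past the threshold.

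Protocol A replicate 2 held only 6 early follicle-like cells by clusters, so the protocols were compared in this class by matching. Protocol A cells were matched to protocol B clusters after the data were seen (n = 3 and 2 libraries, 8166 and 1065 cells). Of cells already named, 93.0% and 98.3% per protocol A library kept their name. The newly named, most of those in replicate 2, were not tested. The insulin pathway kinase gene Akt1 was higher in protocol B by a log2 fold change of 0.86 ± 0.08, and the basement membrane genes trol, vkg and LanA by 0.78 ± 0.04, 0.74 ± 0.05 and 0.73 ± 0.04. Other higher genes were mt:CoII (1.85 ± 0.04), FoxK (1.68 ± 0.13), Slik (1.61 ± 0.07) and the chromatin remodeller gene Chd1 (1.56 ± 0.06). Lower were Uhg7 (-3.82 ± 0.10), RpL22 (-3.40 ± 0.12), mt:ND1 (-3.08 ± 0.09), the innexin gene Inx7 (-2.72 ± 0.14), RpS14b (-2.49 ± 0.05), RpL5 (-2.23 ± 0.05) and ND-23 (-1.06 ± 0.06). Of 7765 tested genes 3958 were past the threshold, 2006 higher and 1952 lower (with library size alone 2902 and 1367, at a median shift of 0.17). Insulin signalling was higher (18 genes, 14 up, 0 down, adjusted p = 0.0148, and 0.246 without protocol A replicate 2), as was the basement membrane (20 genes, 9 up, 1 down, adjusted p = 0.0124), both with the same counts adjusted over the list alone. Ribosomal proteins were lower (85 genes, 10 up, 62 down, and 11 and 63 adjusted over the list alone, adjusted p = 6.2e-24). So was oxidative phosphorylation (71 genes, 13 up, 34 down, and 13 and 35 adjusted over the list alone, adjusted p = 0.0124). The median of the latter changed sign with library size alone, from -0.14 to 0.02. With an estimated correlation all 4 were at adjusted p = 0.728, and the other 21 of 25 lists were not past the threshold.

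The shares of cells per class describe what each preparation recovered, since the sort, the filters and the UMI cut of the files can set them (n = 2 and 3 libraries; exact permutation test over 10 splits, smallest possible p = 0.1). Germline-like cells made up 10.6% and 28.9% of protocol A replicates 1 and 2 and 12.1%, 11.8% and 11.8% of the protocol B libraries (means 19.7 ± 12.9% and 11.9 ± 0.166%; exact p = 0.4). Escort-like cells were 6.77% and 1.92% against 3.03%, 3.02% and 3.25% (exact p = 0.7). Early follicle-like cells were 28.3% and 0.575% against 29.1%, 29.1% and 29.0% (exact p = 0.1). The 0.575% depended on the clustering. With protocol A cells matched to protocol B clusters, replicate 2 had 348 early follicle-like cells in place of 6, mostly untested. Means were then 35.3 ± 2.80% and 29.1 ± 0.0822% (exact p = 0.1), with the difference reversed. Vitellogenic follicle-like cells were 6.09% and 0.479% against 5.38%, 5.50% and 5.24% (exact p = 0.5). The shares of germline-like and vitellogenic cells depended on the setting too. Vitellogenic means were 0.714% and 2.69% with doublets kept, 0.855% and 3.09% at resolution 2, and 1.40% and 5.37% with matched cells (exact p = 0.1 each). Germline-like means were 19.4% and 7.34% at resolution 2, and 20.8% and 7.52% with clusters of low UMI count left out (exact p = 0.1 each). Polar-like cells were 1.41% and 1.73% against 0.568%, 0.537% and 0.700% (exact p = 0.1) and terminal filament/cap-like cells 0.469% and 0.0959% against 0.0928%, 0.161% and 0.177% (exact p = 0.4). Unnamed cells were 46.3%, 66.3%, 49.7%, 49.8% and 49.8%. They included clusters 1 and 18, both led by genes that differed between the protocols such as Uhg7, mt:ND1 and RpL22, at means of 8.14 ± 11.4% and 31.6 ± 44.6% of protocol A and 2.67% and 0% of protocol B. Each protocol A mean rested on 1 library, with 311 cells of cluster 1 from replicate 1 and 1 from replicate 2, and 1 and 658 cells of cluster 18.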

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

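The comparison of clusters 4 and 11 between the protocols and the test on free RNA were chosen after the results were seen. The difference between the protocols was not the same in all germline-like cells. Between clusters 4 and 11 (n = 5 libraries, interaction in edgeR), 935 of 7598 genes had a protocol difference that itself differed, 660 with a larger rise in protocol B in cluster 4 and 275 with a smaller one, with 1881 at an unadjusted p under 0.05. Among the genes with the smallest p were E(spl)m7-HLH, a Notch target (log2 difference 3.26 ± 0.16), the matrix gene SPARC (4.68 ± 0.27), E(spl)m3-HLH (5.16 ± 0.34) and the metallothionein gene MtnA (4.94 ± 0.35). Between germline-like and escort-like cells 187 of 7601 genes had different protocol differences (114 higher and 73 lower in the germline, 1425 at an unadjusted p under 0.05), led by RapGAP1 (-1.75 ± 0.15), Ant2 (-3.25 ± 0.29), Kank (2.34 ± 0.24) and E(spl)m2-BFM (2.42 ± 0.26).

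Escort cell markers summed to 803 ± 243 CPM in cluster 4 of protocol B against 164 ± 26.8 CPM in protocol A, to 630 ± 138 against 458 ± 59.1 CPM in cluster 13, and to 357 ± 10.5 against 424 ± 14.2 CPM in cluster 11. Free RNA in the droplets would raise all 3 clusters if their cells held like numbers of UMIs. The difference in cluster 11 was -66.9 CPM, but its cells had medians of 24185, 25577 and 16797.5 UMIs in the protocol B libraries. Those of cluster 4 had 7283.5, 6695 and 5797, where the same free RNA makes up a larger share. The test therefore cannot decide on free RNA. Escort cells caught in the same droplets as young germ cells, which they enwrap, may explain the rise. This was checked on 135 genes kept out of clustering, with at least 100 CPM in protocol B escort-like cells. They were also picked for at least 10 times their protocol A level in cluster 4, which favours a rise. All 135 were higher in cluster 4 of protocol B, a direction partly set by this choice. The median rise was 11.9% of their level in escort-like cells (quartiles 7.35% to 15.2%), near the 14.8% of the markers. The 10% of cluster 4 cells with the most marker UMIs held 73.1%, 80.2% and 85.8% of these UMIs in the protocol B libraries and 42.9% and 29.7% in protocol A. No biological explanation was tested, and germ cells that express these genes themselves stay open.

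The barcodes of protocol B over the mitochondrial limit, which entered no comparison, carried markers of every class but the gut. Their markers of muscle reached 25.8 CPM on average against 3.61 CPM in the cells kept (7.14-fold), of the fat body 3.52 against 0.965, of the germline 606 against 371, of the terminal filament and cap 17.8 against 11.02 and of escort cells 354 against 265. Tracheal markers were at 1.40 against 0.945 CPM, oviduct markers at 2.01 against 1.40, hemocyte markers at 37.0 against 27.7 and neuron markers at 17.9 against 19.1. Lower than in the cells kept were markers of vitellogenic (4331 against 8755 CPM) and early follicle cells (293 against 399.9), the stalk (57.9 against 88.9) and polar cells (4.09 against 12.6). A floor of 3 counts corresponded to at most 1.39 CPM, so the tracheal and oviduct values lie near it, and over these 3 libraries no test was made.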

How the results depend on the processing

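Library size alone, low-UMI clusters left out, matching, and the alternatives of the 5 added comparisons were chosen after the data were seen. The estimated correlation was planned beforehand as the check of the list tests. Counts that changed by over 1.5 times were those of protocol B against A over all cells without 1 replicate (1880 to 7405 genes against 4239), the same within escort-like cells without 1 replicate (134 to 2100 against 692), without the low-count filter (1269) and with doublets kept (1064), and cluster 13 against cluster 4 without the replicate block (1308 against 2102). In protocol comparisons with 1 library of protocol A left, that library was assumed to vary like the others. Protocols A and B shared no animals or day, so no analysis was paired, and replicate numbers are only names. The difference in share between the protocols changed sign for germline-like cells without protocol A replicate 2 (1.32 points, range -16.9 to 1.32), escort-like cells without protocol A replicate 1 (1.18, range -3.67 to 1.18), vitellogenic follicle-like cells without protocol A replicate 2 (-0.72, range -0.72 to 4.89), terminal filament/cap-like cells without protocol A replicate 1 (0.0479, range -0.325 to 0.0479) and early follicle-like cells with protocol A cells matched (-6.26 against 14.6). For genes named with a fold, 4314 of 4345 results kept direction and call, 31 lost the call, all in comparisons of the protocols, and 0 turned. For gene lists, 1407 of 1507 results kept the call and the direction of the test against all other genes, and 100 lost the call, leaving aside the estimated correlation, with which 110 of 110 lost it. The median fold change of 7 lists changed sign with library size alone: ribosomal proteins in polar-like cells, 4 lists in cluster 11 against cluster 13, oxidative phosphorylation between the protocols in early follicle-like cells, and the proteasome in stalk-like cells. Matching within escort-like cells, terminal filament/cap-like cells at 50 cells or without low-UMI clusters, and stalk-like cells at 50 cells gave no value.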

Other observations

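The comparisons of germline-like clusters and of stalk-like cells, and the tests on the mix of cell classes and on hemocytes, were chosen after the results they concern were seen. The germline-like clusters were compared in the order in which early oogenesis runs, from dividing cysts (cluster 4, led by bam) to cells with synaptonemal complex genes (cluster 13) to later germ cells (cluster 11). In cluster 13 against cluster 4 (n = 5 libraries; 540 and 739 cells), grk, whose product signals from the oocyte to the follicle, rose by a log2 fold change of 4.61 ± 0.22 (93.5 ± 9.04 against 3.78 ± 2.06 CPM), and the replication clamp gene PCNA differed by -2.56 ± 0.09 (84.2 ± 27.1 against 492 ± 133 CPM). With grk rose hb (5.86 ± 0.42), Pde6 (6.12 ± 0.36), Idgf4 (5.30 ± 0.25), the lipoprotein receptor gene LpR2 (3.68 ± 0.26) and the yolk receptor gene yl (1.38 ± 0.10). CycE (-3.43 ± 0.14), dup (-3.48 ± 0.14), RnrL (-2.67 ± 0.10) and Ant2 (-2.62 ± 0.14) were lower, and TfIIA-S-2 held 3 counts against 280 (55.7-fold, counting interval 18.9 to 272). Each direction held in 5 of 5 libraries. Of 3656 tested genes 2102 were past the threshold, 1005 higher and 1097 lower, and 1308 without the library block. With library size alone 1130 were higher and 980 lower.

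DNA replication genes fell from cluster 4 to cluster 13 in 23 of 24 with 0 rising (adjusted p = 2.16e-22, and 0.344 with an estimated correlation), and the proteasome in 33 of 33 (adjusted p = 4.31e-13, and 0.388 with an estimated correlation). Mitosis genes fell (32 tested, 2 up, 22 down, and 2 and 24 adjusted over the list alone, adjusted p = 1.72e-05, and 0.344 with an estimated correlation), as did oxidative phosphorylation (67 tested, 5 up, 46 down, and 5 and 47 adjusted over the list alone, adjusted p = 8.33e-06, and 0.503 with an estimated correlation). Ecdysone signalling (17 tested, 10 up, 1 down, adjusted p = 0.00828, and 0.55 with an estimated correlation) and glutathione enzymes (28 tested, 16 up, 7 down, adjusted p = 0.00726, and 0.344 with an estimated correlation) rose. Yolk and lipoprotein uptake (12 tested, 6 up, 2 down, adjusted p = 0.0482, 0.344 with an estimated correlation, 0.0603 with library size alone) rose. BMP signalling did too (12 tested, 7 up, 1 down, and 7 and 2 adjusted over the list alone, adjusted p = 0.0408, 0.455 with an estimated correlation, 0.0728 without protocol A replicate 2). Other counts were the same adjusted over the list alone, and the other 16 of 24 lists were not past the threshold.

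In cluster 11 against cluster 13 (n = 5 libraries; 988 and 540 cells), the germ plasm gene pgc, which represses transcription in pole cells, rose by a log2 fold change of 3.90 ± 0.09 (250.2 ± 18.1 against 27.0 ± 8.90 CPM), with ZnT35C (3.72 ± 0.10), WRNexo (4.49 ± 0.16), swa (2.32 ± 0.09) and RpS5b (1.98 ± 0.04). Replication genes were higher than in cluster 13, with PCNA at 2.81 ± 0.06 and dup at 3.14 ± 0.14. Genes of recombination and of the synaptonemal complex were lower: mei-P22 (-4.43 ± 0.22), hdm (-3.66 ± 0.17), sunn (-2.99 ± 0.14), c(3)G (-2.92 ± 0.12) and corolla (-2.69 ± 0.11). The BMP genes tkv (-1.36 ± 0.10) and Mad (-1.26 ± 0.06) and the junction genes baz (-1.81 ± 0.06) and shg (-1.15 ± 0.08) fell. All held in 5 of 5 libraries. Of 3572 tested genes 2680 were past the threshold, 1314 higher and 1366 lower (632 and 2415 with library size alone, at a median shift of -0.57).

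Lists with more rises in cluster 11 were DNA replication (24 tested, 20 up, 1 down, adjusted p = 7.64e-06), ribosomal proteins (85 tested, 83 up, 2 down, adjusted p = 1.72e-26) and mitochondrially encoded transcripts (16 tested, 15 up, 0 down, adjusted p = 0.00911, and 0.277 without the library block). Those with more falls were meiosis (20 tested, 2 up, 16 down, adjusted p = 0.000104), BMP signalling (10 tested, 0 up, 9 down, adjusted p = 0.00204) and septate and adherens junctions (24 tested, 3 up, 15 down, adjusted p = 0.0167). The basement membrane (11 tested, 0 up, 10 down, adjusted p = 0.0167, and 0.176 with library size alone), EGFR signalling (16 tested, 1 up, 10 down, adjusted p = 0.0177, and 0.0609 without the library block) and the JNK response (17 tested, 1 up, 10 down, adjusted p = 0.0209, and 0.0623 with library size alone) fell as well. The medians of 4 rising lists changed sign with library size alone: oocyte mRNA localisation (23 tested, 15 up, 5 down, and 15 and 6 adjusted over the list alone, adjusted p = 0.0177, median 0.48 to -0.09), oxidative phosphorylation (67 tested, 49 up, 7 down, adjusted p = 6.46e-06, median 0.42 to -0.15), the proteasome (33 tested, 28 up, 2 down, adjusted p = 8.33e-06, median 0.56 to -0.01) and glutathione enzymes (29 tested, 18 up, 4 down, adjusted p = 0.0177, median 0.36 to -0.20). Escort cell markers were also lower in cluster 11 (424 and 357 CPM in protocols A and B) than in cluster 13 (458 and 630 CPM), so the falls of somatic lists are not separated from a smaller share of somatic RNA. With an estimated correlation all 13 were at adjusted p = 0.583. Other counts were the same adjusted over the list alone, and 11 of 24 lists were not past the threshold.

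At resolution 2, 151 protocol B cells were named stalk-like, the cells that link egg chambers, and were compared with 6057 early follicle-like cells (n = 3 libraries). The transcription factor gene zfh1, a target of JAK-STAT signalling, was higher by a log2 fold change of 8.54 ± 0.13, the receptor gene dome by 2.10 ± 0.10 and Socs36E by 1.72 ± 0.08. Immune genes were raised, with PGRP-SA (9.94 ± 0.39), spz (9.50 ± 0.29), Tep4 (8.98 ± 0.20) and dl (7.71 ± 0.21), and so were the troponin gene TpnC73F (8.85 ± 0.30), CAP (7.53 ± 0.33), the laminin gene wb (6.06 ± 0.10) and the integrin gene mew (3.28 ± 0.09). The stalk-like cluster also had 3 of 9 hemocyte markers detected and raised. The rises of immune genes are therefore not separated from hemocytes, which were not weighed for these cells. PCNA (-4.11 ± 0.22), stg (-3.48 ± 0.17) and armi (-3.12 ± 0.18) were lower, fs(1)Yb held 1 count against 3259 (31.6-fold, counting interval 5.66 to 1247) and Tsp74F 0 against 2308 (at least 7.45-fold). Each direction held in 3 of 3 libraries. Of 3775 tested genes 2265 were past the threshold, 951 higher and 1314 lower (1373 and 904 with library size alone, at a median shift of 0.49).

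Stalk-like cells were higher in JAK-STAT signalling (10 tested, 9 up, 1 down, adjusted p = 0.000119), the JNK response (19 tested, 10 up, 2 down, adjusted p = 0.0015), sarcomere genes (12 tested, 8 up, 2 down, adjusted p = 0.00378), the basement membrane (19 tested, 12 up, 4 down, and 13 and 4 adjusted over the list alone, adjusted p = 0.00415) and yolk and lipoprotein uptake (12 tested, 7 up, 2 down, adjusted p = 0.0153). They were lower in ribosomal proteins (84 tested, 0 up, 83 down, adjusted p = 1.35e-25), oxidative phosphorylation (67 tested, 0 up, 65 down, adjusted p = 8.37e-19), mitosis (32 tested, 0 up, 26 down, adjusted p = 2.98e-06) and DNA replication (24 tested, 0 up, 22 down, adjusted p = 3.01e-06). These 9 lists were at adjusted p = 0.407 with an estimated correlation. So were immune effectors, which were higher (6 tested, 4 up, 0 down, adjusted p = 0.0174, and 0.16 without the low-count filter). The piRNA list (28 tested, 1 up, 14 down, adjusted p = 0.039, 0.561 with an estimated correlation, 0.102 without protocol B replicate 2) was lower. So was the proteasome (32 tested, 0 up, 17 down, adjusted p = 0.0085, 0.482 with an estimated correlation), whose median changed sign with library size alone, from -0.39 to 0.10. Stalk-like cells had a median of 4161 UMIs and 7.70% mitochondrial UMIs, against 9113 to 14675 UMIs and 4.19% to 4.90% in the early follicle-like clusters at resolution 2, so these lists do not separate cell class from RNA quality. For immune effectors the hemocyte markers raised in this cluster are a further limit. Other counts were the same adjusted over the list alone, and 13 of 25 lists were not past the threshold.

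Genes lower in protocol B in every class were the first pattern weighed. Of 6441 genes tested in germline-like, escort-like and early follicle-like cells, 321 were lower and 179 higher in all 3 classes, 500 in all. Of the genes that fell by over 2 in all cells, the 158 also tested in germline-like cells had a median log2 fold change of -2.04 there. For these genes a different mix of classes alone does not account for the falls. The test does not bear on the mix within the class, since cluster 17 made up 0.198% of it in protocol A and 47.4% in protocol B. No other class was used for it. Reads shared with an overlapping gene may account for a few of them, since 6 of the 41 genes that differed by over 1.5 in all 3 classes (14.6%) overlapped another exon on the same strand, against 397 of 6322 others (6.28%; odds ratio 2.56, Fisher's exact p = 0.0425). The other 35 had no such overlap, but included the near-identical copies RpS14a and RpS14b. For them read assignment, kit, sort, day and any software change cannot be told apart. The design held no biological difference.

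The second pattern was the rise of JNK and immune genes in escort-like cells. A response to the longer dissociation of protocol B might raise them, but in protocol A replicate 1 the median of the JNK list lay 1.14 above that of all genes, against 0.694, 1.05 and 0.941 in the protocol B libraries. With 1 protocol A library on this side the test was weak, and a response to dissociation in both protocols stays open. Heat shock genes lay below all genes in the same libraries (-0.467 against -0.246, -0.190 and -0.352). For hemocytes among the escort-like cells, the whole marker list was a weak test, since cluster 13 carries it as well (in 5 of 5 libraries no higher in escort-like cells, 78.2 ± 12.8 against 99.6 ± 13.7 CPM). In escort-like cells it consisted of crq (300 UMIs) and srp (269 UMIs), which early follicle-like cells express too (13.03 and 20.7 CPM). The other 7 hemocyte markers had 0 of 7039468 UMIs over 1022 escort-like cells, while 1 barcode of cluster 0 held 334 UMIs of 6 of them, which argued against hemocytes.

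Other splits of the libraries' sums were fitted with edgeR without the library block. In each of the following comparisons 1 split, the real one, gave as many genes. With 35 splits each, the real split gave 2791 genes for germline-like, 2443 for escort-like, 2114 for vitellogenic follicle-like and 1405 for polar-like against early follicle-like cells, and the highest other split gave 0. Terminal filament/cap-like against escort-like cells gave 395 genes against at most 38 in 35 splits, cluster 13 against cluster 4 gave 1308 against at most 269 in 100 splits, and cluster 11 against cluster 13 gave 2016 against at most 3 in 100 splits. These counts do not settle what chance gives, for 2 reasons. The sums of a library form a pair, and only 8 of the 35 splits, and 12 of the 100, part every library as the real one does, too few for a share under 0.05. The classes and clusters were also formed from these same cells. Stalk-like cells gave 2313 genes against at most 0, and the 10 splits of 3 against 3 sums are too few for a share under 0.05.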
